A study of Homo sapiens with 16 samples.

How the data were processed

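RNA-seq was measured in 16 libraries from a pair of established human melanoma cell lines, SKMEL28 and A375, both of which carry an activating BRAF mutation. The libraries fall into 6 groups. SKMEL28 gave 1 wild-type library (numbered replicate 4), 3 libraries labelled MITFKO and 3 each from clones 3 and 13 of a double knockout (DKO), in which TFE3 had been edited with CRISPR-Cas9 in the MITFKO line. A375 gave 3 wild-type and 3 TFE3KO libraries. Replicates of a group were separate cultures of the same clone or line, so every p-value measures the spread between cultures and not the spread between independently edited clones. Per the labels' protocols, SKMEL28 was grown in RPMI and A375 in DMEM, and the medium was changed before harvest.

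The deposited values were raw read counts per gene, 1 column per library, for 28278 gene symbols. The submitters' processing notes name the aligner STAR, the read counter featureCounts, DESeq2 and the build hg19, with no versions or order of steps; the whole-number counts had not been normalised. The file headers name a STAR output as the input of the count, with input number 38 for 14 libraries, number 3 for the SKMEL28 wild-type library and none for 1 A375 wild-type library. Whether strand was used, which annotation release was counted and how reads with several matches were handled are not given in the sources used here. Values of overlapping or antisense genes, and of families with near-identical copies, are therefore uncertain. These include ribosomal proteins, histones, HLA genes, keratins, zinc finger genes, GAGE1 and SPRR2D. Gene symbols were matched to a GRCh38 RefSeq table for current names and chromosomes only, with 26998 of 28278 matched by symbol and 27656 by symbol or synonym. Because the builds differ, no coordinates are given. GC content was taken from GENCODE transcripts for 96.4% of the genes tested in SKMEL28 and 97.2% of those tested in A375. A list of 24 hypoxia-induced genes, used only in the closing section, was written after some of its members had been seen.

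Total counts per library ran from 17320855 to 31269126. CPM values, counts relative to library size, were computed here from the counts with trimmed-mean (TMM) scaling. A value of 0 is bounded by a floor of 3 counts summed over the group's libraries. Folds against a group at 0 are given as "at least", and folds against 1 to 3 counts as a ratio with its 95% counting interval. Sequencing reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

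Counts were tested with edgeR 4.0.16 in R 4.3.3: low counts were filtered with filterByExpr by group, libraries were scaled with TMM factors, and each gene was tested with the robust quasi-likelihood F-test. Adjusted p throughout means Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The words rose and fell are kept for called genes and called lists. The SKMEL28 comparisons came from 1 model of its 10 libraries (14605 genes), A375 from a model of its 6 libraries (14012 genes), and the difference between lines from a joint model of 15 libraries (15093 genes). The lone SKMEL28 wild-type library was assumed to vary like the other groups. The comparisons were MITFKO against wild type, each DKO clone and their mean against MITFKO, clone 13 against clone 3, A375 TFE3KO against wild type, and the difference between the TFE3 effects of both lines.

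A total of 22 gene lists were fixed before the data were examined, as were the design, the comparisons and the alternatives, except those named as added. They covered CLEAR lysosome, autophagy, folliculin and Rag GTPases, melanocyte differentiation, invasive melanoma state, extracellular matrix, integrin and focal adhesion, EMT transcription factors and cadherins, neural crest and lineage, cell cycle, glycolysis, oxidative phosphorylation, ATF4 stress response, cholesterol synthesis, interferon and antigen presentation, MAPK output, TGF-beta and YAP output, keratinocyte, fibroblast, and leukocyte and endothelium markers, ribosomal proteins and replication histones. Some lists share members: the invasive list shares 6 genes with the TGF-beta and YAP list, and the fibroblast markers share 5 with the matrix list. Each list was tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 22 lists of a comparison. The same test with a correlation estimated for each list is printed for the calls that it ended, beside them or in the next sentence. Camera compares a list with the other genes, so its direction can differ from the sign of the list's median.

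The genes named were chosen by a rule fixed in advance: MITF, TFE3, TFEB and TFEC in every comparison; the 5 largest rises and 5 largest falls among called genes with a mean CPM of at least 5 in the higher group and no overlap between the libraries of both groups; and up to 3 called members of each list with the smallest adjusted p. For TFE3 editing in SKMEL28 the ranking used the change averaged over both clones, among genes called the same way in each clone. For clone 13 against clone 3 and for the difference between lines, the 3 largest differences each way were taken. Genes on chromosome Y and XIST were left out.

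The models were tested on simulated counts in which a known set of genes had been changed. For MITFKO against wild type (14117 genes), 13.8% of genes changed 1.25-fold and 85.7% of those changed 2-fold were recovered. For clone 3 (14118 genes) these shares were 31% and 90.7%. For clone 13 (14107 genes) they were 42.2% and 81.4%, and 10.3% of its calls were false. For A375 (13824 genes) they were 51.6% and 95.7%, and for the difference between lines (14630 genes) 14% and 75.6%. Small changes were thus the least often recovered where the lone wild-type library or both lines entered.

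Groups share replicate numbers 1 to 3, with no statement in the sources that a number marks a shared day or batch. Across 12 pairs of same-numbered libraries, the correlation across genes of their deviations from their group means ran from -0.0799 to 0.367, and 3 pairs exceeded 0.1. These 3 were the pairs of clone 3 and clone 13 (0.141, 0.367 and 0.153), so that by the rule set in advance the numbers paired only these groups. Replicates 1 and 3 of these clones were not told apart by number, since their unmatched pairs had 0.13 and 0.152; only replicate 2 stood out. Comparisons that share control libraries were set beside 50 simulations of unchanged groups.

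Alternatives were median-of-ratios and upper-quartile scaling, no filter or a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, only the groups compared, leaving out each library in turn, an adjusted p under 0.01 and an absolute log2 fold change of at least 1. Leaving out the libraries numbered 2 of one or both DKO clones, and leaving out genes on shifted chromosomes, were added after seeing the data.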

Results

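Transcripts were counted in 16 RNA-seq libraries from the human melanoma lines SKMEL28 and A375 to ask what the transcription factor TFE3 contributes when its relative MITF has been edited, and what it contributes in a line whose MITF was not edited. The SKMEL28 groups were wild type (1 library), the line labelled MITFKO (3 libraries), and clones 3 and 13 of the MITFKO/TFE3KO double knockout, abbreviated DKO (3 libraries each). The A375 groups were wild type and TFE3KO (3 libraries each). Totals ran from 17320855 counts in replicate 3 of DKO clone 3 to 31269126 in replicate 1 of A375 TFE3KO, with 23177517 in the SKMEL28 wild-type library. The SKMEL28 libraries detected from 15605 to 17360 genes and the A375 libraries from 16885 to 17528. All values below are TMM-scaled counts relative to library size (CPM, mean ± SD, n = 3 except the lone wild-type SKMEL28 library), and folds carry adjusted p-values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

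MITF, TFE3, TFEB and TFEC form a family of transcription factors with closely related DNA-binding domains. MITF drives pigment cell genes, and TFE3 and TFEB drive lysosomal genes under the control of mTORC1. TFE3 was lower in every library edited for it, but to different degrees. It averaged 73.4 ± 3.72 CPM in the libraries labelled MITFKO, 9.37 ± 1.8 in clone 3 and 45.7 ± 2.88 in clone 13, leaving 12.8% of the MITFKO level in clone 3 (log2 fold change -2.97 ± 0.109 SE, adjusted p = 1.92e-14) and 62.4% in clone 13 (-0.68 ± 0.093, adjusted p = 4.15e-06), where it was close to the 43.7 CPM of the wild-type library. In A375 it went from 125 ± 5.91 to 12.1 ± 0.709 CPM, 9.74% of wild type (-3.36 ± 0.067, adjusted p = 1.73e-40). MITF mRNA was not lower in the libraries labelled MITFKO: it stood at 498 ± 29.7 CPM against 524 in wild type (log2 fold change -0.07 ± 0.086 SE, adjusted p = 0.516). Counts over a whole gene include transcripts of an edited allele, so neither this value nor the TFE3 level of clone 13 measures protein, and neither the MITFKO label nor the TFE3KO label of clone 13 was checked by these data.

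TFE3 itself rose in the libraries labelled MITFKO, relative to wild type (log2 fold change 0.75 ± 0.136 SE, adjusted p = 8.44e-05). MITF mRNA rose when TFE3 was edited in SKMEL28, to 781 ± 28.9 CPM in clone 3 (0.65 ± 0.061, adjusted p = 3.67e-08) and 870 ± 64.3 CPM in clone 13 (0.81 ± 0.061, adjusted p = 9.77e-10). In A375 it went the other way, from 36.3 ± 4.25 to 18.9 ± 0.799 CPM (-0.94 ± 0.088, adjusted p = 3.93e-13). TFEB was scarce, at 1.31 to 2.75 CPM by group. It fell in A375 TFE3KO from 2.75 ± 0.871 to 1.49 ± 0.342 CPM (adjusted p = 0.0268), a call that ended without A375 wild-type replicate 3 (adjusted p = 0.235), TFE3KO replicate 2 (0.0608) or TFE3KO replicate 3 (0.0857). It was not called in any SKMEL28 comparison (adjusted p = 0.976 for MITFKO, 0.626 for clone 3 and 0.701 for clone 13). TFEC averaged at most 0.275 CPM in any group and was too low to test.

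**Figure D1:**
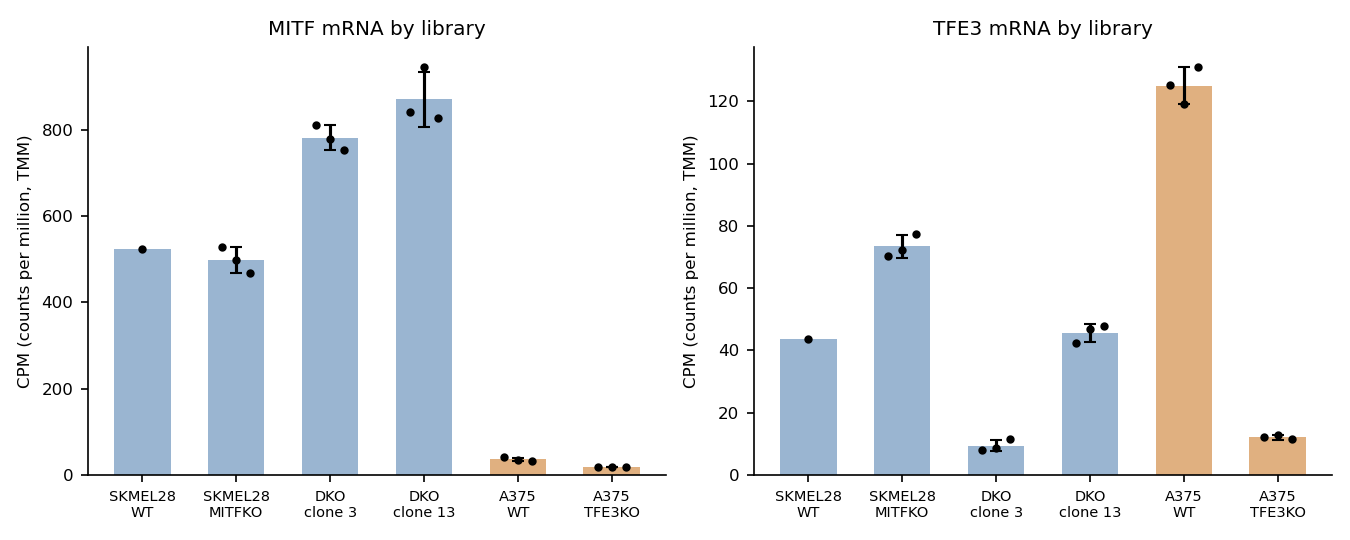
Scaled counts (CPM) of MITF and TFE3 in each of the 6 groups; bars are group means, points are libraries and error bars are SD (none for the single SKMEL28 wild-type library). MITF stays at 498 CPM in the group labelled MITFKO against 524 CPM in wild type, and TFE3 averages 9.37 CPM in clone 3 but 45.7 CPM in clone 13.

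The first comparison asked how the line labelled MITFKO differs from SKMEL28 wild type. The libraries labelled MITFKO had lower pigment cell, cell cycle and respiratory chain genes, and higher genes of the invasive melanoma state, of the ATF4 stress response and of ERK signalling. With an estimated correlation the pigment cell, invasive and ERK lists kept their call, and the cell cycle, respiratory chain and ATF4 lists did not (adjusted p = 0.26, 0.238 and 0.05). Of 14605 genes, 3676 were higher and 3424 lower, 2456 of them at least doubled or halved. NRP1, a co-receptor for semaphorins and VEGF, went from 0.638 to 133 ± 3.09 CPM (log2 fold change 7.69 ± 0.161 SE, adjusted p = 2.57e-19), and CDH1, the epithelial cadherin, from 31.2 to 0.177 ± 0.11 CPM (-7.40 ± 0.404, adjusted p = 3.57e-11). In the pigment cell list QPCT was 6.78-fold lower, and RAB27A, which moves melanosomes, and the kinase gene CDK2, both known MITF targets, were 3.03-fold and 2.93-fold lower.

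The largest rises that did not overlap between groups were SHISAL1 (at least 44.0-fold higher), CD74, the invariant chain of MHC class II (0.199 to 142 ± 6.87 CPM), NRP1, the secreted peptide gene ADM2 (0.199 to 41.5 ± 5.3 CPM) and the growth factor binding protein IGFBP3 (11.8 to 2060 ± 81.8 CPM). The largest falls were the organic anion transporter SLCO2B1 (a 2840-fold ratio on 1 count in the libraries labelled MITFKO, interval 509 to 112000), the sulfotransferase SULT1C2 (1930-fold, interval 345 to 76100), ARMCX2 (at least 163-fold lower), ZNF492 (at least 107-fold lower) and the vesicle protein RPH3A (69.3 to 0.14 ± 0.201 CPM).

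Of 28 measured melanocyte differentiation genes, 25 fell and 2 rose (adjusted p = 1.65e-12, and 0.037 with an estimated correlation). Here and below, where no second count is given, the count adjusted over the list alone was the same. The invasive melanoma list went up, with 25 of 34 genes higher and 3 lower (26 and 3 adjusted over the list alone; adjusted p = 6.77e-09, and 0.0173 with an estimated correlation). Its median log2 change was 2.16, or 2.09 with genes near the floor at their bound. Besides NRP1 it included the non-canonical ligand WNT5A (1.56 to 69.6 ± 1.05 CPM) and the laminin receptor subunit ITGA3 (18.4 to 316 ± 20 CPM). MAPK output rose in 15 of 18 genes and fell in 1 (adjusted p = 8.9e-08, and 0.0173 with an estimated correlation), among them the feedback inhibitor SPRY4 (5.22-fold), the AP-1 subunit FOSL1 (5.71-fold) and the cyclin CCND1 (4.49-fold). In the ATF4 list 19 of 20 genes rose and 1 fell (adjusted p = 5.91e-12, and 0.05 with an estimated correlation, which missed the threshold). ATF4 itself, the master transcription factor of the integrated stress response, was 4.15-fold higher, the pseudokinase TRIB3 9.66-fold and the transcription factor CEBPB 4.78-fold.

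The lysosome and autophagy genes, classical targets of TFE3 and TFEB, were also higher in the libraries labelled MITFKO. In the CLEAR lysosome list 24 of 41 genes rose and 3 fell (24 and 5 adjusted over the list alone; adjusted p = 0.000405, but adjusted p = 0.417 with an estimated correlation). Examples were the hydrolases CTSB (2.49-fold) and TPP1 (2.39-fold). Autophagy genes rose in 18 of 27 cases and fell in 1 (adjusted p = 5.97e-05, and 0.0437 with an estimated correlation), led by the receptors NBR1 (2.25-fold) and CALCOCO2 (1.98-fold) and the ATG8 family member GABARAPL1 (2.62-fold). Folliculin and Rag GTPase genes, which relay amino acid supply to mTORC1, split into 7 higher and 6 lower of 26 (adjusted p = 0.833), with the leucine sensor SESN2 up 5.73-fold and the folliculin partner FNIP2 down 2.73-fold.

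Cell cycle genes fell in 28 of 30 cases (29 adjusted over the list alone; adjusted p = 1.65e-12, but adjusted p = 0.26 with an estimated correlation), including the replication clamp PCNA (3.11-fold lower), the spindle checkpoint kinase BUB1 (2.57-fold) and BIRC5, which encodes survivin (2.43-fold). Respiratory chain genes fell in 17 of 26 cases (adjusted p = 1.11e-05, but adjusted p = 0.238 with an estimated correlation), such as UQCRFS1 (1.99-fold lower) and ATP5F1C (1.85-fold). Cholesterol synthesis genes fell in 14 of 22 (adjusted p = 0.000597, but adjusted p = 0.0883 with an estimated correlation), with ACAT2 4.04-fold lower. Matrix genes rose in 16 of 35 cases and fell in 5 (adjusted p = 0.00524, but adjusted p = 0.38 with an estimated correlation), with the collagenase MMP1 at 109 ± 3.8 CPM against 2.35 and SPARC 3.13-fold higher.

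The other lists were not called as a whole. TGF-beta and YAP output had 12 genes higher and 6 lower of 20 (adjusted p = 0.148), with PMEPA1, a TGF-beta feedback regulator, 22.4-fold and the ligand TGFB1 14.1-fold higher. Integrin and focal adhesion genes had 14 higher and 6 lower of 28 (adjusted p = 0.0622), with ZYX 3.24-fold higher. EMT factors and cadherins had 6 higher and 3 lower of 9 (adjusted p = 0.109), with ZEB1, a repressor of CDH1, 9.81-fold and CDH2 2.96-fold higher. Neural crest genes had 9 higher and 7 lower of 21 (adjusted p = 0.716), with DLX2 6.19-fold higher and S100B 1.78-fold lower. Their median was 0.00 and their mean 0.82. Glycolysis genes had 8 higher and 2 lower of 20 (adjusted p = 0.0675). Interferon and antigen presentation genes had 4 higher and 1 lower of 20 (3 and 1 adjusted over the list alone; adjusted p = 0.607), with HLA-B 3.26-fold higher. Ribosomal proteins split into 8 higher and 9 lower of 29 (adjusted p = 0.688), and replication histones had 6 higher of 13 (adjusted p = 0.0675). Markers of keratinocytes (2 higher and 1 lower of 6; 3 and 1 adjusted over the list alone), fibroblasts (2 higher of 6; 1 adjusted over the list alone) and leukocytes or endothelium (1 lower of 4; none adjusted over the list alone) had adjusted p = 0.655, 0.683 and 0.908. The comparison rests on 1 wild-type library, whose file header also names a different alignment input from the others. ATF4 lies on chromosome 22 and TGFB1 on chromosome 19, whose genes had median log2 changes of 0.214 and 0.295, and ACAT2 and HLA-B on chromosome 6, with a median of -0.383. Fold changes of this comparison rose with GC content (Spearman correlation 0.232). Once that trend was removed, chromosomes 22, 19 and 6 had medians of 0.047, 0.051 and -0.322.

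**Figure D2:**
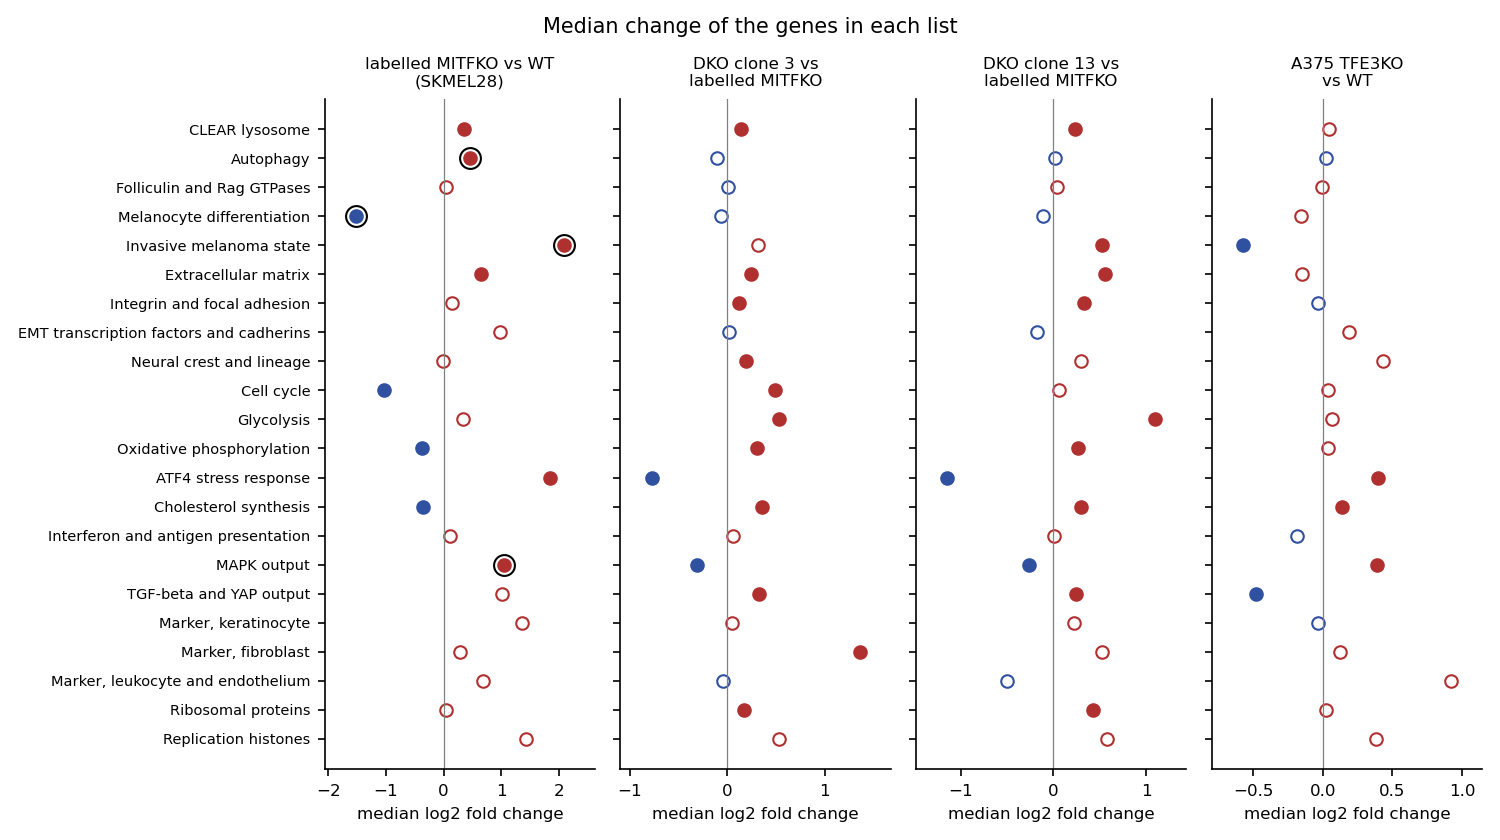
Median log2 fold change of each gene list in 4 comparisons (horizontal axis, ranges differ between panels), with genes near the counting floor at their bound; red and blue mark the direction of the camera test, filled points a call with the preset correlation and black rings a call kept with an estimated correlation. The ATF4 list has a median of 1.845 in MITFKO against wild type, -0.776 in clone 3 and -1.144 in clone 13 against MITFKO, and 0.398 in A375.

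The second comparison asked what the additional editing of TFE3 changed in the line labelled MITFKO. Both DKO clones had lower ATF4 stress genes and ERK-dependent genes, and higher glycolytic, respiratory, ribosomal, matrix and adhesion genes, than the libraries labelled MITFKO. None of the 14 list calls of this comparison was kept with an estimated correlation (adjusted p = 0.0997 to 0.469). DDIT3, the stress-induced factor also called CHOP, went from 84.4 ± 5.51 CPM to 22.1 ± 0.604 in clone 3 and 17.2 ± 1 in clone 13 (log2 fold change over both clones -2.11 ± 0.0697 SE, adjusted p = 8.44e-16), and TRIB3 from 226 ± 8.06 to 72.5 ± 2.38 and 71.7 ± 5.26 (-1.65 ± 0.0523, adjusted p = 6.45e-16). Averaged over both clones, 2975 of 14605 genes were higher and 3025 lower. Most changes were small: 556 genes at least doubled or halved, and the median absolute log2 change of called genes was 0.39.

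Clone 3 differed from MITFKO in 5240 genes (2665 higher, 2575 lower) and clone 13 in 5951 (2994 higher, 2957 lower). In both clones 1675 genes were higher and 1566 lower, where independent lists of these sizes would share 546.3 and 521.3, and 186 went opposite ways where 1067 would be shared. Because both clones were compared with the same MITFKO libraries, part of the excess may come from these controls, which were too few to split. Simulated unchanged clones shared 0.16 genes on average. Such clones have hardly any called genes, so this count cannot show how much the shared controls add between clones that did change. The covariance of the fold changes was 0.274 against 0.0611 simulated (0.0527 to 0.0673). Their correlation was r = 0.532, against 0.488 simulated (0.444 to 0.521), and among genes of at least 5 CPM r = 0.658, against 0.495 (0.468 to 0.538).

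**Figure D3:**
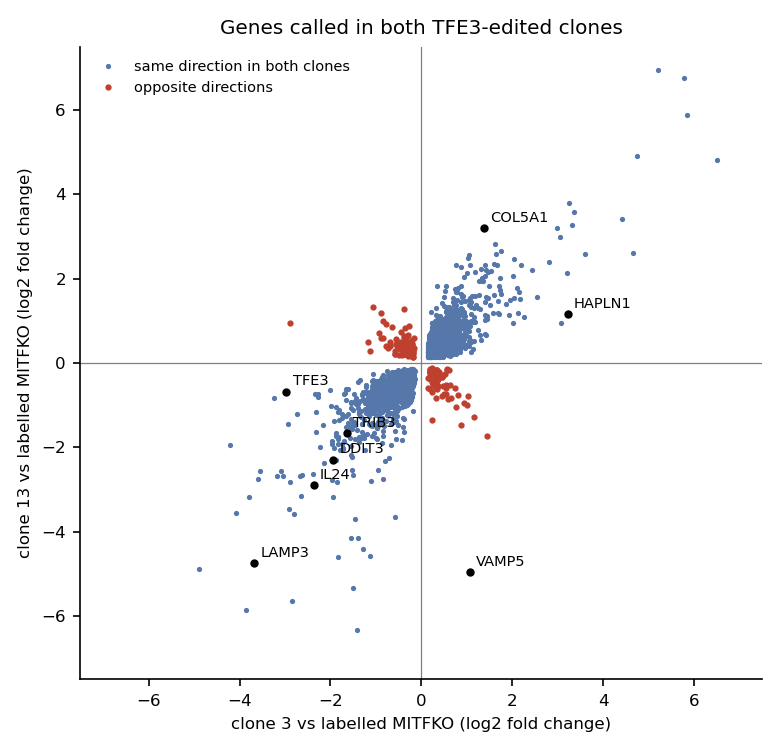
Log2 fold change against MITFKO in clone 3 (horizontal) and clone 13 (vertical) of the genes called in both, 1 point per gene, with named genes marked; the most extreme points rest on groups near 0 counts. A total of 3241 genes lie on the same side of 0 in both clones and 186 on opposite sides, and TFE3 lies at -2.97 and -0.68.

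The largest rises called in each clone were ATP6V0A4, a subunit of the vacuolar proton pump (0.566 ± 0.101 CPM in MITFKO, 5.34 ± 0.945 in clone 3 and 2.5 ± 0.115 in clone 13), the fibrillar collagen gene COL5A1 (4.3 ± 0.177, 11.3 ± 0.552 and 39.7 ± 3.92 CPM), BEND5 (3.01 ± 0.433, 9.37 ± 2.12 and 21.3 ± 6.29 CPM), TMEM178B (4.61-fold) and the hyaluronan link protein HAPLN1 (0.653 ± 0.254, 6.13 ± 1.16 and 1.47 ± 0.142 CPM). The largest falls were LAMP3, a stress-induced lysosomal membrane protein (16.3 ± 1.04 CPM in MITFKO, 1.27 ± 0.317 in clone 3 and 0.594 ± 0.369 in clone 13), ZNF320 (6.17 ± 1.23, 2.8 ± 0.573 and 0.264 ± 0.23 CPM), PRR9 (7.20-fold), the fatty acid receptor GPR84 (7.03-fold) and CST7, which encodes cystatin F (6.27-fold).

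Among the ATF4 stress genes 16 of 20 fell in each clone, and over both clones 16 fell and 1 rose (adjusted p = 5.43e-11, but adjusted p = 0.0997 with an estimated correlation). CEBPB was 2.17-fold lower, and SESN2, which the folliculin and Rag list shares with this one, 2.39-fold lower. MAPK output fell in 13 of 18 genes and rose in 2 (adjusted p = 0.000262, but adjusted p = 0.0997 with an estimated correlation), such as the ERK phosphatases DUSP4 and DUSP6 (each 1.53-fold lower) and the ETS factor ETV5 (1.58-fold). Glycolysis genes rose in 16 of 20 and fell in 2 (17 and 2 adjusted over the list alone; adjusted p = 5.43e-11, but adjusted p = 0.258 with an estimated correlation), with PGAM1, ENO1 and LDHA 1.92-fold, 1.92-fold and 1.96-fold higher. Replicate 2 of clone 13 and of clone 3 stood above the mean of their other replicates in this list, by medians of 0.342 and 0.174 log2 units.

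Respiratory chain genes rose in 22 of 26 and fell in 3 (adjusted p = 2.63e-06, but adjusted p = 0.244 with an estimated correlation), for example COX7A2 (1.43-fold) and NDUFA4 (1.34-fold). Ribosomal protein genes rose in 25 of 29, with RPL35 1.42-fold and RPL7A 1.35-fold higher (adjusted p = 1.41e-10, but adjusted p = 0.299 with an estimated correlation). Cell cycle genes rose in 15 of 30 and fell in 1 (adjusted p = 5.89e-05, but adjusted p = 0.469 with an estimated correlation), with BIRC5 1.74-fold and BUB1 1.65-fold higher. In clone 3 alone 23 of 30 rose (24 adjusted over the list alone; adjusted p = 3.09e-10, but adjusted p = 0.319 with an estimated correlation). In clone 13 alone 7 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.371, and 0.000661 without clone 13 replicate 2, whose cell cycle genes lay below those of its other replicates by a median deviation of -0.418). Cholesterol synthesis genes rose in 12 of 22 and fell in 1 (adjusted p = 0.000518, but adjusted p = 0.11 with an estimated correlation).

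Matrix genes rose in 18 of 35 and fell in 5 (adjusted p = 0.000266, but adjusted p = 0.258 with an estimated correlation). Besides COL5A1 they included LAMB1 (1.56-fold) and COL9A3 (889 ± 42.1 CPM in MITFKO, 1770 ± 148 in clone 3 and 1780 ± 193 in clone 13). Integrin and focal adhesion genes rose in 14 of 28 and fell in 2 (adjusted p = 0.00021, but adjusted p = 0.0997 with an estimated correlation), with ITGA4 1.74-fold and ITGB1 1.51-fold higher. The invasive list rose in 15 of 34 genes and fell in 5 (17 and 5 adjusted over the list alone; adjusted p = 0.00135, but adjusted p = 0.0997 with an estimated correlation), including the matrix glycoprotein TNC (1.54-fold) and CAV1 (1.49-fold). TGF-beta and YAP output rose in 10 of 20 and fell in 3 (adjusted p = 0.0174, but adjusted p = 0.244 with an estimated correlation), with TGFBI 2.34-fold and ID3 1.44-fold higher. Neural crest genes rose in 11 of 21 and fell in 4 (adjusted p = 0.0331, but adjusted p = 0.258 with an estimated correlation), with SOX5 2.02-fold higher.

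CLEAR lysosome genes were higher in the DKO clones: 21 of 41 rose and 3 fell (21 and 4 adjusted over the list alone; adjusted p = 0.000198, but adjusted p = 0.375 with an estimated correlation), and 15 rose in each clone. LAMP2 was 1.42-fold and GALNS 1.74-fold higher. Autophagy genes were not called as a list, with 4 higher and 10 lower of 27 (5 and 10 adjusted over the list alone; adjusted p = 0.308). The phosphoinositide-binding protein WIPI1 was 1.60-fold, ATG14 1.69-fold and the autophagy receptor SQSTM1 1.27-fold lower. Folliculin and Rag genes split into 6 higher and 8 lower of 26 (7 and 8 adjusted over the list alone; adjusted p = 0.923). Melanocyte differentiation genes split into 7 higher and 12 lower of 28 (7 and 13 adjusted over the list alone; adjusted p = 0.185), with the melanosome receptor GPR143 lower (43.3 ± 1.18 CPM in MITFKO, 6.51 ± 0.709 in clone 3 and 18.8 ± 0.783 in clone 13) and the melanosome glycoprotein GPNMB 1.52-fold higher.

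Of the remaining lists, EMT factors and cadherins had 3 higher and 3 lower of 9 (3 and 4 adjusted over the list alone; adjusted p = 0.923), with ZEB1 1.30-fold lower. Interferon genes had 2 higher and 2 lower of 20 (adjusted p = 0.661) and replication histones 2 higher of 13 (1 adjusted over the list alone; adjusted p = 0.143). Keratinocyte markers had 3 higher and 1 lower of 6 (adjusted p = 0.387), with a median of 0.14, a mean of -0.02 and KRT15 at 30.7 ± 3.85 and 34.3 ± 5.13 CPM. Leukocyte and endothelial markers had 1 lower of 4 (adjusted p = 0.452). Fibroblast markers, a list of 12 of which 5 are also in the matrix list, rose in 3 of 6 genes (adjusted p = 0.0259, but adjusted p = 0.258 with an estimated correlation and 0.0534 without clone 13 replicate 2). LUM went from 48.3 ± 4.65 to 92.6 ± 1.79 CPM in clone 3 and 72.1 ± 5.07 in clone 13, beside 39.6 CPM in wild type. QPCT, CRIM1, ITGA4 and BUB1 lie on chromosome 2, whose genes had a median log2 change of -0.186 in clone 13.

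Clones 3 and 13 share a genotype label but differed from each other in 4036 genes (2084 higher and 1952 lower in clone 13). TFE3 was 4.89-fold higher in clone 13, and MITF was close in both (log2 difference 0.16 ± 0.061 SE, adjusted p = 0.0592, and 0.0224 with a replicate block). The vesicle fusion proteins VAMP5 and VAMP8 were nearly absent from clone 13, at 0.253 ± 0.0967 CPM against 16.9 ± 1.96 in clone 3 and 0.722 ± 0.258 against 10.5 ± 1.59. The transporter gene SLC5A4 was 8.41-fold lower there. The neuronal pentraxin NPTX1 (12.8 ± 2.54 CPM in clone 3, 56.6 ± 41.5 in clone 13; adjusted p = 0.0287) and the hypoxia-induced carbonic anhydrase CA9 (6.24 ± 3.04 and 27 ± 17 CPM; adjusted p = 0.0279) were higher in clone 13. Both calls ended without clone 3 replicate 1 (adjusted p = 0.1 and 0.0941) or clone 3 replicate 3 (0.0939 and 0.0779), and that of NPTX1 also without clone 3 replicate 2 (0.0639). They also ended with limma-voom (0.0828 and 0.0727) and with only the groups compared (0.0806 and 0.0771). Without clone 13 replicate 2 the log2 differences went from 2.15 to 1.36 for NPTX1 and from 2.11 to 1.47 for CA9, so this library carried much of their size. Glycolysis was higher in clone 13 in 17 of 20 genes (18 adjusted over the list alone), ribosomal proteins in 24 of 29 (26), matrix genes in 14 with 4 lower of 35 (16 and 5), invasive genes in 14 with 8 lower of 34 (16 and 8) and integrin genes in 12 with 5 lower of 28 (12 and 6). Cell cycle genes were lower in 18 of 30 (22 adjusted over the list alone) and ATF4 stress genes in 11 of 20 (13). These 7 lists had adjusted p from 1.06e-11 to 0.0324, and each had adjusted p = 0.469 with an estimated correlation. Clone 13 replicate 2 stood apart in glycolysis and cell cycle genes in the directions of these differences, and without it the 7 lists kept their calls (adjusted p = 2.13e-15 for glycolysis and 1.89e-09 for cell cycle).

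Changes also followed chromosomes. In clone 13 the 529 tested genes of chromosome 4 had a median log2 change of -0.376 against MITFKO (95% bootstrap interval -0.415 to -0.316), with 252 lower and 35 higher. Of the genes placed in order along it, the first 154 had a median of -0.174 (interval -0.231 to -0.119) and the other 360 of -0.464 (-0.536 to -0.416). In clone 3 the median of this chromosome was -0.019. In A375 TFE3KO, chromosome 13 had a median of 0.31 (139 of 259 genes higher, 9 lower) and chromosome 18 of -0.262 (102 of 198 lower, 17 higher).

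**Figure D4:**
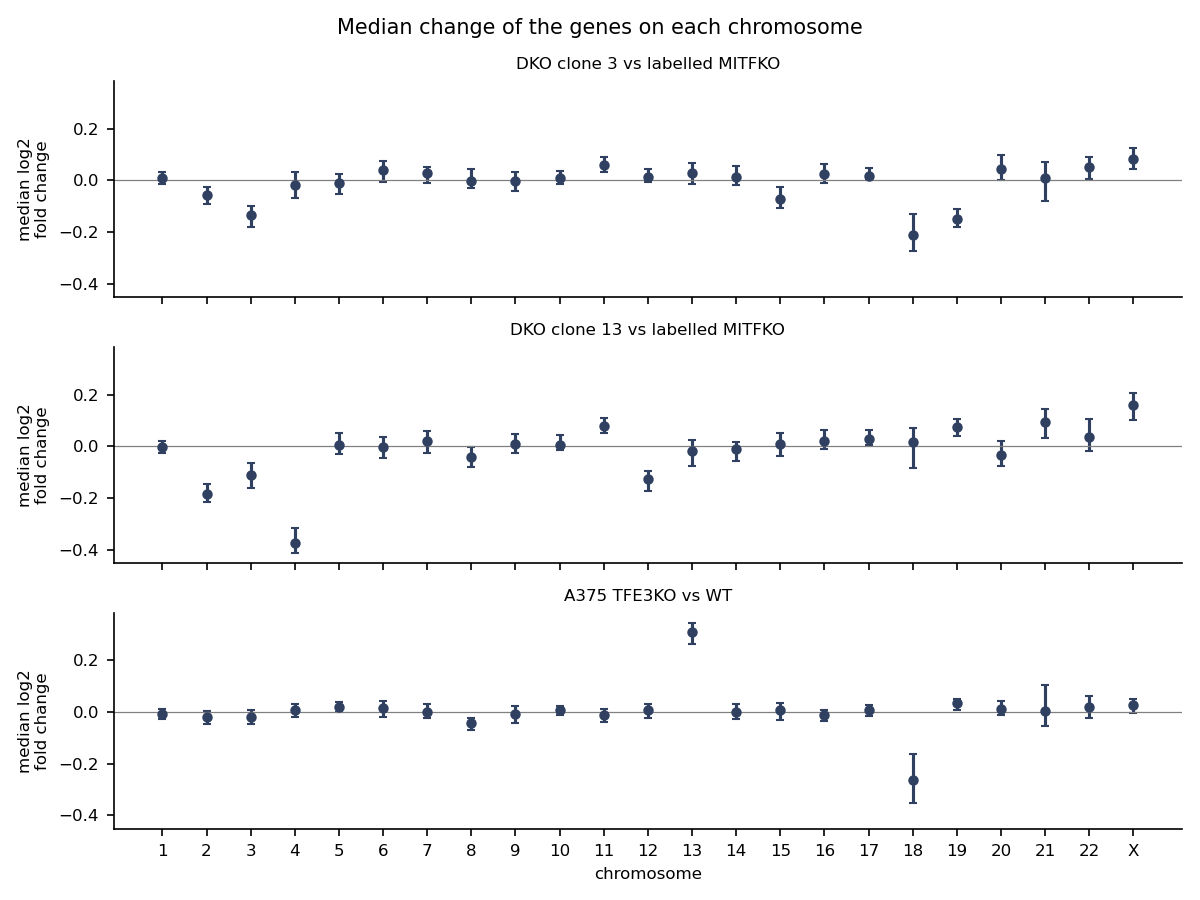
Median log2 fold change of the tested genes of each chromosome in clone 3 and clone 13 against MITFKO and in A375 TFE3KO against wild type; points are medians and bars 95% bootstrap intervals. Chromosome 4 lies at -0.376 in clone 13, and chromosomes 13 and 18 lie at 0.31 and -0.262 in A375 TFE3KO.

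The third comparison asked what TFE3 editing changed in A375, which was not edited for MITF. A375 TFE3KO had lower genes of the invasive state and of TGF-beta and YAP output, and higher ATF4 stress response genes and ERK-dependent genes, though none of these calls was kept with an estimated correlation (adjusted p = 0.229, 0.229, 0.229 and 0.345). In the invasive list 26 of 34 genes fell and 4 rose, and SPRY4, the ERK feedback inhibitor, went from 48.7 ± 3.45 to 232 ± 18.9 CPM (log2 fold change 2.25 ± 0.0545 SE, adjusted p = 1.16e-28). TFAP2B, a neural crest transcription factor, went from 12.3 ± 1.1 to 106 ± 3.74 CPM (3.11 ± 0.0711, adjusted p = 5.59e-38). Of 14012 genes, 2991 were higher and 3083 lower, 1281 at least doubled or halved.

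The largest rises were the extracellular matrix protein FREM1 (0.308 ± 0.15 to 8.83 ± 0.402 CPM), the protocadherin PCDH7 (2.57 ± 0.848 to 35.3 ± 1.71 CPM), the calcium-binding protein TESC (12.7-fold), SPRR2D (12.3-fold) and the ion exchanger SLC24A3 (12.1-fold). The largest falls were BASP1 (at least 302-fold lower, from 12.9 ± 1.45 CPM), the endophilin SH3GL2 (at least 240-fold), the cancer-testis antigen GAGE1 (at least 135-fold), the receptor phosphatase PTPRD (693-fold on 1 count in TFE3KO, interval 124 to 27400) and the cytokine IL6, from 15.9 ± 1.44 to 0.0312 ± 0.0541 CPM (558-fold, interval 154 to 4610).

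The invasive list had adjusted p = 7.49e-12 (but adjusted p = 0.229 with an estimated correlation), with the guidance ligand SLIT2 3.96-fold lower. SERPINE2 and TNC, other members of this list, were 2.74-fold and 1.83-fold higher. TGF-beta and YAP output fell in 14 of 22 genes and rose in 5 (14 and 6 adjusted over the list alone; adjusted p = 0.000102, but adjusted p = 0.229 with an estimated correlation). The matricellular YAP target CCN1 was 2.34-fold, the receptor kinase AXL 1.72-fold and TGFBI 1.65-fold lower. ATF4 stress genes rose in 14 of 20 and fell in 4 (adjusted p = 0.00014, but adjusted p = 0.229 with an estimated correlation), with the serine synthesis enzymes PHGDH and PSAT1 2.03-fold and 1.79-fold and the cystine transporter SLC7A11 2.16-fold higher. MAPK output rose in 11 of 18 and fell in 3 (adjusted p = 0.00158, but adjusted p = 0.345 with an estimated correlation), with SPRY2 2.13-fold higher and EPHA2 1.76-fold lower. Cholesterol synthesis genes rose in 9 of 21 and fell in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.0307, but adjusted p = 0.229 with an estimated correlation).

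No call was made for CLEAR lysosome genes as a list, with 14 higher and 8 lower of 40 (14 and 9 adjusted over the list alone; adjusted p = 0.455); CTSZ was 1.65-fold higher and the lysosomal cholesterol exporter NPC1 1.45-fold lower. Autophagy genes had 7 higher and 5 lower of 27 (adjusted p = 0.913; median 0.03, mean -0.04, test direction down). SQSTM1 went from 907 ± 5.28 to 507 ± 12.9 CPM (1.79-fold lower) and OPTN, another autophagy receptor, was 2.01-fold lower. Folliculin and Rag genes had 7 higher and 6 lower of 26 (7 and 7 adjusted over the list alone; adjusted p = 0.913; median -0.01, mean 0.11, test direction up), with SESN3 3.63-fold higher. Melanocyte genes had 5 higher and 3 lower of 18 (adjusted p = 0.666; median -0.16, test direction up), with the lineage factor SOX10 1.57-fold and EDNRB 3.49-fold higher. Neural crest genes had 12 higher and 5 lower of 21 (adjusted p = 0.0556), including ERBB3 (2.74-fold) and SOX5 (2.84-fold).

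Matrix genes had 13 higher and 18 lower of 34 (15 and 18 adjusted over the list alone; adjusted p = 0.666; median -0.15, mean -0.14, test direction up). TIMP3, an inhibitor of metalloproteinases, went from 602 ± 15.5 to 2140 ± 22.8 CPM and the laminin chain LAMA4 from 46.8 ± 1.17 to 243 ± 7.42 CPM. Integrin genes had 10 higher and 11 lower of 28 (10 and 13 adjusted over the list alone; adjusted p = 0.736), with ITGB3 2.85-fold higher. EMT factors and cadherins had 6 higher and 4 lower of 11 (adjusted p = 0.603), with CDH2 1.72-fold lower and PRRX1 2.21-fold higher. Cell cycle (9 higher and 6 lower of 30; 10 and 7 adjusted over the list alone), glycolysis (8 and 5 of 20; 8 and 6 adjusted over the list alone), respiratory chain (5 and 2 of 26; 4 and 2 adjusted over the list alone) and ribosomal protein genes (5 and 2 of 29; 5 and 1 adjusted over the list alone) had adjusted p = 0.655, 0.565, 0.611 and 0.565. Interferon genes had 3 higher and 8 lower of 22 (adjusted p = 0.565), with HLA-B 2.14-fold higher and IRF1 1.93-fold lower. Replication histones had 3 higher and 1 lower of 15 (adjusted p = 0.565). Markers of keratinocytes (1 higher and 2 lower of 6), fibroblasts (2 and 2 of 7; 3 and 2 adjusted over the list alone; median 0.12, mean -0.23) and leukocytes or endothelium (2 and 1 of 5) had adjusted p = 0.666, 0.951 and 0.603. EDNRB and SPRY2 lie on chromosome 13 and NPC1 and CDH2 on chromosome 18, the shifted chromosomes of this comparison.

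The last comparison tested whether TFE3 editing changed a gene differently in SKMEL28 (mean of both clones against MITFKO) and in A375. The effect differed in 5693 of 15093 genes, 2786 more positive in SKMEL28 and 2907 more positive in A375. The test is set against the spread between cultures, not between independently edited clones. MITF differed by 1.68 ± 0.095 SE log2 units (adjusted p = 1.25e-13), and TFE3, less depleted on average in the SKMEL28 clones, by 1.55 ± 0.118 (adjusted p = 1.89e-11). The TFE3 difference came mostly from clone 13 (log2 fold change -0.68), since clone 3 (-2.97) lay near A375 (-3.36). Of 35 invasive genes, with a median of 0.43 in the DKO clones and -0.57 in A375 TFE3KO, 23 were more positive in SKMEL28 and 4 in A375 (adjusted p = 2.15e-08, and 0.0139 with an estimated correlation). TGF-beta and YAP output was also more positive in SKMEL28 (15 and 2 of 22; adjusted p = 4.18e-05, and 0.016 with an estimated correlation). ATF4 stress genes were more positive in A375 in 17 of 20 cases and in SKMEL28 in 2 (adjusted p = 4.98e-13, and 0.0139 with an estimated correlation), and MAPK output in 12 of 18 and 1 (13 and 1 adjusted over the list alone; adjusted p = 6.64e-07, and 0.0139 with an estimated correlation). AXL rose in clone 3 from 3 counts summed over the MITFKO libraries to 62 (a 23.9-fold ratio, interval 7.81 to 119), while it was 1.72-fold lower in A375 TFE3KO.

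**Figure D5:**
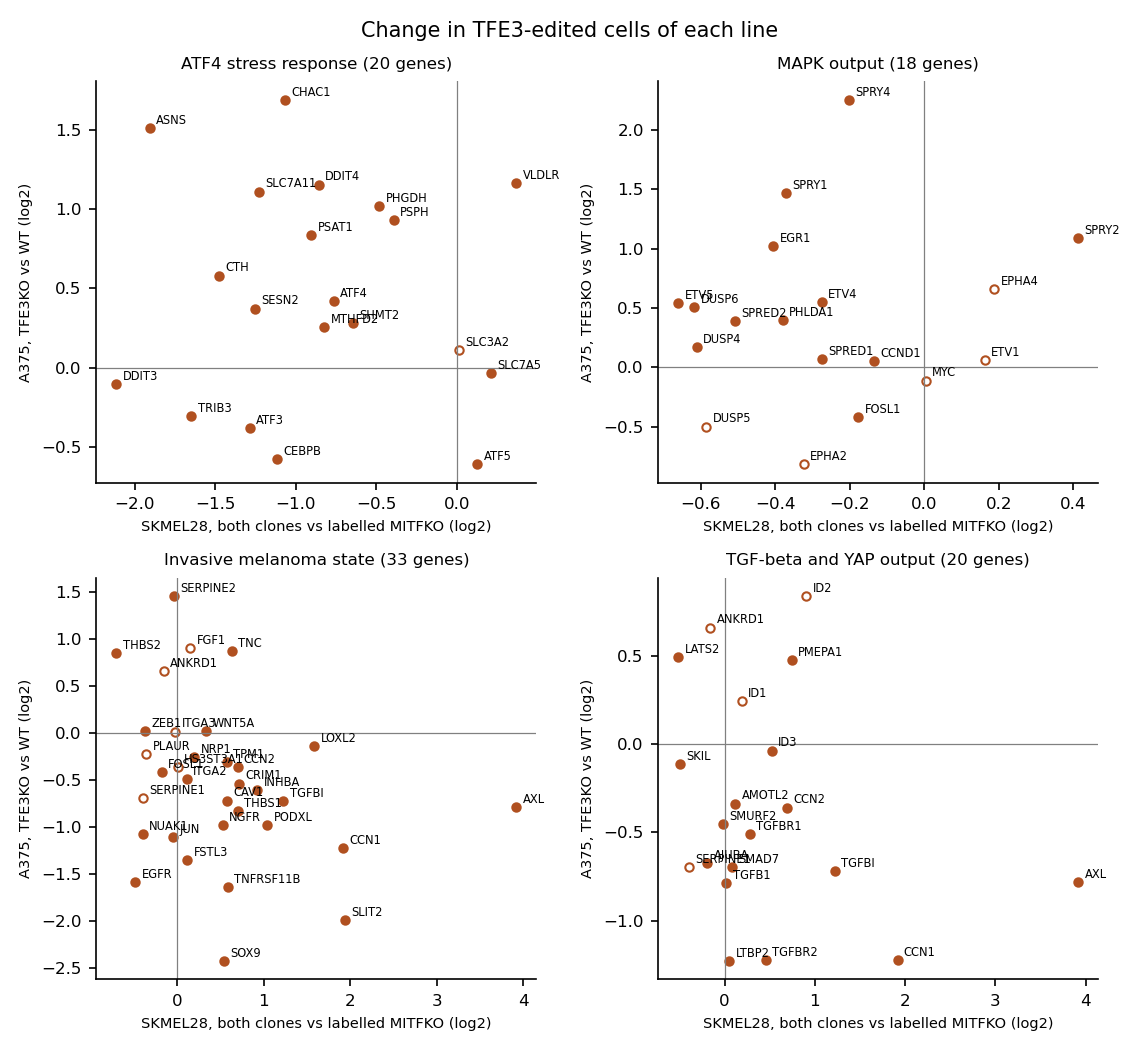
Log2 fold change with TFE3 editing in SKMEL28 (both clones against MITFKO, horizontal) and A375 (TFE3KO against wild type, vertical) for the members of 4 lists, 1 point per gene; filled points differ between lines at an adjusted p under 0.05. ATF4 genes lie mostly left of 0 and above it (medians -0.881 and 0.398) and invasive genes mostly right of 0 and below it (medians 0.429 and -0.573).

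Glycolysis (16 more positive in SKMEL28 and 1 in A375 of 20; 17 and 1 adjusted over the list alone), ribosomal proteins (23 of 29; 25 adjusted over the list alone), respiratory chain (15 and 3 of 26; 16 and 3 adjusted over the list alone), cell cycle (10 of 30) and integrin genes (15 and 6 of 29; 15 and 7 adjusted over the list alone) were also more positive in SKMEL28. Their adjusted p was 8.57e-09, 6.15e-08, 0.000817, 0.00186 and 0.00791, but with an estimated correlation adjusted p = 0.399, 0.436, 0.382, 0.58 and 0.121. CLEAR lysosome genes had 12 and 2 of 41 (adjusted p = 0.0507, and 0.58 with an estimated correlation). The adjusted p of this list was 0.0313 with median-of-ratios scaling and 0.0467 with a replicate block, but 0.0656 with upper-quartile scaling. Without clone 13 replicate 2 the list had adjusted p = 0.117, and without replicate 2 of both clones 0.174. The largest single differences were in genes near 0 in one line, such as the membrane skeleton protein EPB41L3 (adjusted p = 1.2e-08), which was absent from A375 TFE3KO and at 69.2 to 89.1 CPM in the SKMEL28 groups edited for MITF. Among 12979 genes tested in both lines, 867 were higher in both and 706 lower in both, where independent lists would share 619.4 and 619.8, and 1311 went opposite ways where 1239 would be shared (Fisher's exact test of direction, p = 2.48e-06, over genes that are not independent). The correlation of the fold changes across these genes was r = 0.0738.

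Changes in the libraries labelled MITFKO and changes on editing of TFE3 were also set against each other, since both comparisons share the MITFKO libraries with opposite sign. Of the genes called in MITFKO against wild type and in each clone, 1456 went opposite ways and 657 the same way, where independent lists would share 786.8 opposite. The covariance of the fold changes was -0.0956, against -0.0607 (range -0.0754 to -0.0389) for simulated unchanged clones, and their correlation was r = -0.112, against -0.134 (-0.167 to -0.0862). By clone the covariance was -0.153 for clone 3 against -0.0603 simulated, and -0.0385 for clone 13 against -0.0611. The ATF4 genes had a median of 1.845 in MITFKO against wild type, -0.881 in the DKO clones against MITFKO and 0.877 in the DKO clones against wild type.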

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

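The tests of the chromosome 4 genes in clone 3, along the chromosome and by expression, of scaling between the lines, of replicate 2 of the libraries labelled MITFKO, of A375 RNA in clone 13 replicate 2, and of the line difference without the replicates numbered 2 were chosen after the result was seen, as was the hypoxia list.

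The change with TFE3 editing differed between the SKMEL28 and A375 cells in 5693 genes, by the test of the difference itself. That test measures the spread between cultures, and clones 3 and 13 of SKMEL28 differed from each other in 4036 genes. It therefore cannot separate a difference between the lines from one between the particular edited cells. Among the genes named for TFE3 editing in either line, 107 of 129 differed, against 37.7% of all genes, but they had been picked for large or clear changes within a line, so a high share follows from the choice. The lists that differed were ATF4 stress response (adjusted p = 4.98e-13), glycolysis (8.57e-09), invasive melanoma state (2.15e-08), ribosomal proteins (6.15e-08), MAPK output (6.64e-07), TGF-beta and YAP output (4.18e-05), oxidative phosphorylation (0.000817), cell cycle (0.00186) and integrin and focal adhesion (0.00791). With an estimated correlation ATF4, invasive and MAPK (adjusted p = 0.0139 each) and TGF-beta and YAP (0.016) kept the call, and glycolysis (0.399), ribosomal proteins (0.436), oxidative phosphorylation (0.382), cell cycle (0.58) and integrin genes (0.121) did not. MITF differed by 1.68 and TFE3 by 1.55 log2 units. Of the largest single differences, BASP1 (adjusted p = 5.47e-07) and SH3GL2 (0.00197) were lost from A375 TFE3KO and near 0 in SKMEL28, and EPB41L3 (1.2e-08) was lost from A375 TFE3KO and kept in SKMEL28. SH3GL2 had adjusted p = 1 without clone 3 replicate 1 or clone 13 replicate 1. IRX6 (8.63e-08), MAPK4 (4.45e-05) and RUNX1T1 (0.000343) were the largest the other way. IRX6 and MAPK4 had 0 counts in A375 wild type. RUNX1T1 was near 0 in every SKMEL28 group, with 7 counts summed over the MITFKO libraries and 0 in the DKO clones.

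For 4 of these lists (invasive, TGF-beta and YAP, ATF4 and MAPK), the median changes with TFE3 editing had opposite signs in the 2 lines; with an estimated correlation the difference stayed called, but the change within either line was not (adjusted p = 0.0997 to 0.345). Scaling between libraries, which moves all lists alike, was argued against as the cause by median differences on both sides of 0, with a gap of 2.39 from highest to lowest; this test replaced a count of calls under other scalings. All 4 stayed called without replicate 2 of both clones. A state peculiar to the MITFKO libraries cannot be told apart: ATF4 genes of the DKO clones lay above wild type by a median of 0.877, which met the bound set in advance against it, but that bound rests on the lone wild-type library and ignored a partial return from MITFKO (1.845). MITF editing, the line, its medium and the particular edited cells all changed together between the lines. A dependence on MITF may thus be one candidate explanation among these and was not tested. By mRNA, A375 was also the line with less MITF, at 36.3 CPM in wild type against 498 in the libraries labelled MITFKO. MITF protein was not measured here in either line.

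Clones 3 and 13 differed from each other in 4036 genes. The lists were glycolysis (adjusted p = 1.06e-11), ribosomal proteins (1.01e-10), cell cycle (1.23e-10), ATF4 stress response (7e-06), extracellular matrix (0.0024), invasive melanoma state (0.026) and integrin and focal adhesion (0.0324), and each had adjusted p = 0.469 with an estimated correlation. The genes were TFE3 (2.29 log2 units higher in clone 13), NPTX1 (2.15), CA9 (2.11), VAMP5 (-6.03), VAMP8 (-3.88) and SLC5A4 (-3.07). VAMP5 and VAMP8 are neighbours in the RefSeq table.

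Genes of chromosome 4 were lower in clone 13 (median -0.376). An effect that TFE3 editing brings to both clones was argued against by clone 3, whose median was -0.019, and a GC trend as the whole cause by a median of -0.3 after its removal. An equal loss of the whole chromosome was argued against by 10 blocks of genes in RefSeq order. The first 3 had a median of -0.174 (95% bootstrap interval -0.231 to -0.119) and the other 7 of -0.464 (-0.536 to -0.416). This cut was placed after the block medians were seen, so the gap between its parts is partly chosen. Genes of low, middle and high expression had medians of -0.544, -0.394 and -0.275, and those of the other 7 blocks differed from genes of other chromosomes at the same expression level by -0.505, -0.434 and -0.443. Fewer copies of that later part may be the cause, but its blocks were picked for being low and DNA was not measured, so this cannot be told apart from a change of regulation along the chromosome.

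Replicate 2 of both DKO clones stood apart from its sister cultures. Hypoxia-induced genes deviated upward by a median of 0.468 in clone 13 replicate 2 (21 of 23 genes) and 0.263 in clone 3 replicate 2 (21 of 22), and CA9 reached 46.5 CPM in clone 13 replicate 2 against 19.0 and 15.5 in the others. A condition common to all SKMEL28 cultures numbered 2 was argued against by MITFKO replicate 2 (median -0.074), a GC trend by a median of 0.502 after its removal, and A375 RNA by marker genes at 0.09% of their A375 level. The last test replaced one with a bound that was missed: those genes stood 1.59 times higher in clone 13 replicate 2 than in the other replicates. Denser or less oxygenated DKO cultures may be a candidate explanation; the sources used here give no density, and no biological explanation was tested.

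Other splits of the libraries were counted for each comparison of 3 or more libraries. For clone 3 (5240 genes), clone 13 (5951), clone 13 against clone 3 (4036) and A375 (6074), the real split was the 1 of 10 that called this many genes, and the highest other called 0. With 10 splits a share under 0.05 cannot be reached. For the mean of both clones, 1 of 100 splits gave as many as 6000 genes, and the highest other gave 2023, from the split with the clone 13 libraries as controls. For calls shared by the clones, 1 of 100 gave 3241, against 889 in that same split. For the difference between lines, 1 of 100 gave 5693. The highest other gave 4337, from a split that kept the real groups apart but exchanged their roles. Most other splits mixed cultures from different groups, and their median was 0 genes for each of the last 3 results. The real split thus stood out because cultures of a group resemble each other. These splits cannot exclude ordinary differences between clones or lines as the source of the last 3 results.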

How the results depend on the processing

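Leaving out the replicates numbered 2 of one or both DKO clones and leaving out genes on shifted chromosomes were chosen after seeing the data. Of 3380 values of named genes under the alternatives, 3349 kept their side of the threshold. Another 25 lost their call, 6 gained one and 0 reversed the direction of a call. Most of these genes had been picked for large or clear changes, so a high share kept follows from the choice. Of 594 list tests, 515 kept their side of the threshold, 67 lost their call, 12 gained one and 0 reversed a call. Values and lists without a call could change direction and still count as kept. The A375 list tests could not change where only DKO libraries were left out, and they count as kept too. The calls lost were those of NPTX1, CA9, TFEB, KRT6A, LUM, CD68, H2AC6 and SH3GL2 under some alternatives, and MITF in clone 13 against clone 3 gained one. In MITFKO against wild type, LUM was not called without MITFKO replicate 1 (adjusted p = 0.137) or 2 (0.0772), nor CD68 without MITFKO replicate 1 (0.0832), 2 (0.0626) or 3 (0.0648). In A375, H2AC6 was not called without wild-type replicate 1 (0.166) or TFE3KO replicate 1 (0.115). Every count of called genes stayed within 1.5 times under the other scalings, filters, tools and left-out libraries.

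Stricter thresholds moved the counts by construction. With an absolute log2 fold change of at least 1, MITFKO against wild type kept 2456 genes, clone 3 549, clone 13 763, both clones 556, clone 13 against clone 3 455, A375 1281 and the difference between lines 1426; calls shared by both clones numbered 215 and by both lines 67. With an adjusted p under 0.01, clone 13 against clone 3 kept 2481. The covariance of MITFKO and DKO changes, -0.0956, was -0.0307 among genes of at least 5 CPM (simulated -0.00696, range -0.0121 to -0.0032), -0.153 for clone 3 and -0.0385 for clone 13, the last above its simulated -0.0611; the cause was not tested. Of 69 list calls among 154 tests, 8 were kept with an estimated correlation.

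By the pairing check, replicate numbers paired only clone 13 with clone 3, where the replicate block gave 4410 genes against 4036. Over all comparisons 6 of 15 libraries correlated best with a library of their own number, each of them from these clones except MITFKO replicate 1. Elsewhere the libraries shared only a number, and the block gave 5575 genes for clone 3, 6221 for clone 13, 6290 for both, 5721 for A375 and 5674 for the difference between lines. There the block ended the list calls of neural crest genes in both clones (adjusted p = 0.0574) and clone 3 (0.0582), of fibroblast markers in both clones (0.0522) and of TGF-beta and YAP output in clone 13 (0.0666), and added one for CLEAR lysosome genes in the difference between lines (0.0467). In the paired comparison the block changed no call of a list and, among the named genes, only that of MITF. No paired analysis was possible for MITFKO against wild type because the wild-type library is numbered 4. The lone wild-type library could not be left out, and restricting the fit to the groups compared changes nothing for A375 and has no equivalent for the difference between lines. At this depth TFEC was too low to test.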

Other observations

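The genes described here were chosen after their values were seen, as those with the largest changes called the same way in A375 TFE3KO, clone 3 and clone 13, and no further test was run on them. FLT1, a VEGF receptor, rose by log2 changes of 3.05 in A375, 1.47 in clone 3 and 2.17 in clone 13, from 14.1 to 117 CPM in A375. The transcription factor gene MAF rose by 1.94, 1.16 and 1.31, the monooxygenase-like MOXD1 by 1.38, 1.40 and 1.44, the glycosyltransferase GALNT2 by 0.94, 0.94 and 0.97, and the ligand BMP6 by 1.00, 1.09 and 1.34. SOX5, COL9A3, HAPLN1, CORO2B and ATP6V0A4 rose in all 3 comparisons as well.

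Among genes that were lower in all 3 comparisons, the cytokine gene IL24 changed by -1.88 in A375, -2.36 in clone 3 and -2.90 in clone 13, and the stress-induced cytokine GDF15 by -1.74, -2.38 and -2.63. In SKMEL28 these genes had gone from 0.638 to 113 CPM and from 0.478 to 43.7 CPM between wild type and the libraries labelled MITFKO. NRROS changed by -2.08, -1.73 and -1.31, the endosomal protein gene PLEKHF1 by -1.09, -1.75 and -1.92, the growth factor genes PDGFA by -1.16, -1.09 and -1.74 and FGF2 by -1.36, -1.01 and -0.90, and the interferon-inducible PARP14 by -0.89, -0.88 and -1.17. SYT14, ARHGEF4 and GATA6 were also lower in each. These genes stood against a background in which the lines shared little: across 12979 genes the fold changes had a rank correlation of 0.053.

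Besides chromosome 4 in clone 13, other chromosomes had shifted medians. In MITFKO against wild type, chromosome 6 had a median log2 change of -0.383 (265 of 649 genes lower), chromosome 2 of -0.2, chromosome 22 of 0.214 and chromosome 19 of 0.295; the last 2 stood at 0.047 and 0.051 once a trend on GC content was removed. Clone 3 had a median of -0.212 on chromosome 18, and clone 13 of -0.186 on chromosome 2 and 0.158 on chromosome X.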
